A study of Mus musculus with 22 samples.

How the data were processed

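Total RNA from lungs of A/J mice was labelled and hybridised to Affymetrix mouse expression arrays, 1 array per sample, per the labels. The 22 arrays fall into 8 groups of exposure (cigarette smoke or air) by time (5 hr, 8 days, 1.5 months and 6 months). The deposited values are 1-colour intensities per probe set on a linear scale. On all 22 arrays their mean after trimming 2% of the values at each end is 500, so each array had been scaled as a whole before deposit. The software behind these values is not given in the sources used here, and no detection calls were used. Per the labels each array is 1 lung sample, but nothing states how cages, litters or days were shared. P-values therefore measure the spread between these samples, part of which may be technical.

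The intensities were used as deposited, on the log2 scale, with 2 zero values set to the lowest positive value, 0.1. No further normalization was applied. From 45101 probe sets, 64 Affymetrix controls were left out, and then the 40% with the lowest mean log2 value, which lay below a signal of 109. This left 27022 probe sets. The annotation table gave 34945 probe sets exactly 1 gene symbol, 932 several and 9160 none; only those with 1 symbol were named. No symbol changed when updated through its gene identifier. A gene is represented by its probe set with the highest mean over all arrays, which gave 13016 genes, and other probe sets that were called in the opposite direction are mentioned.

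Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend) in 1 model of the 8 group means over all 22 arrays, with 14 residual degrees of freedom and no covariate. All groups share 1 estimate of the spread because none has more than 3 arrays. The single 5 hr CS array is thereby assumed to vary like the arrays of the other groups. Contrasts were CS minus Air at each time, the mean of the differences at 8 days, 1.5 months and 6 months, the change of the difference between those times, and the change over time in Air lungs. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 over all probe sets tested. The count that also changed at least 1.5-fold, the fold in the design text of the series, is given beside it. Every adjusted p of a gene comes from limma.

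Before the data were examined, 48 gene lists were fixed, 24 of pathways and 24 of cell types of the lung or adjoining tissue. They were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, with adjustment over the 48 lists at each time. Members were counted as passing over all genes tested and when adjusted over the list alone. The model was tested on simulated data: at 8 days 40 of 50 probe sets changed 2-fold were recovered, at 1.5 months 33, at 6 months 35 and at 5 hr 20. Simulated values had the same mean and spread in every group and no session or sex-linked effect. The counts at 8 days, 1.5 months and 6 months therefore differ only by the random draw. Far fewer probe sets were changed than were called in the data. The genes named were set by a rule that was also fixed before the data were examined. At 8 days, 1.5 months and 6 months these are the 12 largest rises and 8 largest falls among called genes whose 3 CS arrays lie beyond the 3 Air arrays. At 5 hr they are the 5 largest rises and 5 largest falls. Added to these are up to 4 members, by p, of each list that was called or had a called member, and the 6 genes with the smallest interaction p. Other genes named were members of a list or were chosen after their values were seen.

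The per-array experiment records gave hybridisation sessions for 8 days, 1.5 months and 6 months, and none at 5 hr. The 8-day Air and CS arrays were hybridised in separate sessions. At 1.5 and 6 months 1 session held the 3 Air arrays and 1 CS array, and another held 2 CS arrays, so session could be fitted as a block there. Measures of array quality were compared with exact permutation tests. Alternatives were quantile normalization, median centring, an offset of 32 before log2, other filters, variance models and array weights, 1 probe set per gene, the arrays of the compared groups alone, the replicate number and the session as blocks, and leaving out each array in turn. A rule close to the one in the design text was also run (at least 6 of 9 pairwise comparisons, a 1.5-fold change and an unadjusted p under 0.05). Alternatives chosen after seeing the data were those that leave out the 8-day arrays or replace the 8-day Air arrays by the 1.5-month Air arrays, those of the Air lungs over time, the lists without a filter and the lists with session as a block. The R package data.table (version 1.17.8) handled the tables, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15. At most 3 arrays per group limit the precision, and no array was left out of the main comparisons.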

Results

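Gene expression was measured in lungs of A/J mice, an inbred strain, that had breathed cigarette smoke (CS) or air for 5 hr, 8 days, 1.5 months or 6 months. Each RNA sample was hybridised to 1 Affymetrix mouse expression array, which gave 22 arrays. Every group had 3 arrays except CS at 5 hr, which had 1. The deposited intensities were scaled to the same trimmed mean of 500 on every array. The median signal of single arrays lay between 144.3 on the 5 hr CS array and 256.8 on an 8-day Air array. The 8-day Air group averaged 241 ± 16.1 (SD, n = 3). Arrays of the same group correlated with Pearson's r between 0.948 and 0.983 across probe sets. After the filter on dim probe sets, 27022 probe sets and 13016 genes were tested. The number of arrays per group limits the precision of every value below.

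The first question was what differed between the single CS array and the 3 Air arrays at 5 hr. The CS array also differed from the Air arrays in sex-linked signal (below), so smoke cannot be told apart from other differences between these animals. At 5 hr the enzymes that oxidise tobacco hydrocarbons were the genes with the largest rise: Cyp1a1 went from a mean signal of 183 in Air lungs to 11459 on the CS array, a 62.6-fold rise. Cyp1b1, a second cytochrome of the same route, rose 21.8-fold, from 299 to 6517. Hmox1, the haem oxygenase that is induced by oxidants, rose 21.6-fold, from 498 to 10764. Il1r2, a decoy receptor for interleukin-1, rose 11.6-fold from a dim Air signal of 69.1, and Maff, a small Maf transcription factor, rose 11.3-fold. These 5 genes had the largest rises among genes whose CS value lay beyond all 3 Air values. Their limma adjusted p ranged from 2.6e-12 for Cyp1a1 to 1.13e-05 for Il1r2.

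Targets of the aryl hydrocarbon receptor, which binds such hydrocarbons, were called upward as a list at 5 hr. Of 5 measured members, 4 rose and 1, Nfe2l2, fell by 0.58 on the log2 scale; adjusted over the list alone the counts were also 4 and 1. Besides both cytochromes, Tiparp, a repressor of the receptor, rose 2.21 ± 0.13 (SE) on the log2 scale, and Aldh3a1, an aldehyde dehydrogenase, rose 3.35 ± 0.46. Among 30 genes of the Nrf2 and glutathione list, 22 rose, 7 did not pass and 1, the epoxide hydrolase gene Ephx1, fell; adjusted over the list alone, 23 rose. Txnrd1, thioredoxin reductase, rose 4.74-fold and Srxn1, sulfiredoxin, rose 9.78-fold. The log2 rise of Gclc, a subunit of the enzyme that starts glutathione synthesis, was 2.60 ± 0.15. Camera, the limma test of a gene list against all other genes, gave adjusted p = 6.83e-07 for the receptor targets and 6.39e-22 for the Nrf2 list. With an estimated correlation, the adjusted p was 0.00301 for both lists.

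Acute stress genes also rose at 5 hr. Of 21 immediate early genes, 15 rose and none fell (16 adjusted over the list alone), among them the AP-1 members Fosl2, at 3.24-fold, and Junb, at 3.60-fold. Of 15 glucocorticoid response genes, 11 rose and none fell (13 adjusted over the list alone). Fkbp5, a co-chaperone of the glucocorticoid receptor, rose 5.16-fold, and Sgk1, a kinase, rose 2.15-fold. In the p53 and apoptosis list, 9 of 18 genes rose and 2 fell (9 and 3 adjusted over the list alone). Cdkn1a, the cell cycle inhibitor p21, rose 6.12-fold, and Pmaip1, the death effector Noxa, rose 3.52-fold. Of 20 genes of the unfolded protein and integrated stress list, 7 rose and 2 fell (9 and 2 adjusted over the list alone). Examples were Ddit4, an inhibitor of mTORC1, at 3.98-fold, and Atf4, a transcription factor, at 2.10-fold. Adjusted p with an estimated correlation was 0.0277, 0.0232, 0.0072 and 0.0412 for these lists in turn. Both metallothionein genes, Mt1 and Mt2, rose 6.62-fold and 7.63-fold, although their list of 4 genes had camera adjusted p = 0.0547.

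Further lists at 5 hr were called only at the preset correlation. Of 10 neutrophil markers 5 rose (9 adjusted over the list alone), including Ngp, a granule protein gene, at 5.92-fold; the list had adjusted p = 0.135 with an estimated correlation. The matching value was 0.135 for neutrophil chemokines and acute phase genes, of which 3 of 8 rose (5 adjusted over the list alone), among them Lcn2, an iron-sequestering protein gene, at 2.00-fold. Of 22 proteasome genes 12 rose (14 adjusted over the list alone), such as Psmd12 at 1.65-fold, with adjusted p = 0.139 with an estimated correlation. Of 20 protease and inhibitor genes 5 rose, also when adjusted over the list alone, such as Adam8 at 1.70-fold, with adjusted p = 0.0888 with an estimated correlation. Of 18 mitochondrial respiration genes 2 rose, for example Ndufv1, with adjusted p = 0.888 with an estimated correlation. The adipocyte list, with Pnpla2 risen of 6 members, and the cardiac muscle list, with no member of 12 passing, were called at the preset correlation. They had adjusted p = 0.743 and 0.888 with an estimated correlation. Acta1, of skeletal muscle, read 467.5 on the CS array against 6236 ± 2510 (SD, n = 3) in Air lungs.

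Lists of resident cells were not called at 5 hr: the endothelial list had 3 risen and 5 fallen of 18 (camera adjusted p = 0.66), the fibroblast list 2 fallen of 13 (0.514), the dendritic cell list 3 of 12 (0.563) and the ciliated cell list 4 of 15 (0.582). Single members that changed are given next. Sox18 and Sox17, transcription factors of endothelium, were -1.91 and -1.48 on the log2 scale, and Kdr, a receptor for vascular endothelial growth factor, fell by 1.02. Lyve1, a hyaluronan receptor of lymphatic endothelium, rose 2.36-fold. Tcf21, a transcription factor of lung mesenchyme, fell by 1.93, Ccr2, a chemokine receptor of monocytes, at -2.79, and Zbtb46, a transcription factor of dendritic cells, at -2.07. Foxj1, which directs the formation of motile cilia, fell by 1.13. Lox, which crosslinks elastin and collagen, rose 3.98-fold, and Eln, the elastin gene, rose 3.95-fold; their extracellular matrix list had 3 risen, 2 fallen and 22 not passing of 27 and was not called (adjusted p = 0.466). Of 18 clock genes 4 rose and 4 fell, and the list was not called (adjusted p = 0.501). Among them, Dbp fell by 2.43 and Arntl rose 5.26-fold.

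The falls named by the rule at 5 hr were those of Rtp3, Zswim3, Fam25c, Atg16l2 and Npy1r. On the CS array Rtp3 read 3.8, Zswim3 10.3, Atg16l2 13.8 and Npy1r 19.6, below the array's 20th percentile of 31.7, against 356, 217, 217 and 237 in Air lungs. The size and order of these falls are therefore not given. Among probe sets with a mean signal above 200, the CS array held 13 that lay more than 2 log2 units below every other array. The 8-day Air arrays held 5 to 9 such probe sets and all remaining arrays 0 to 3. Those of Rtp3 and Atg16l2 were among the losses on the CS array. Fam25c lost its call with other scalings and without Air 1 or Air 2 (adjusted p = 0.0724 and 0.0934). In all, 6201 of 27022 probe sets were called at 5 hr, 2173 higher and 4028 lower; 4773 of them also changed at least 1.5-fold. On the gene level 1033 genes were called higher and 2236 lower. With each array centred on its median, the split was 3395 higher and 1811 lower, and the median difference of all probe sets moved from -0.10 to 0.13 on the log2 scale. A single CS array gives no replicate of its own; the test assumed that it varied like the other groups. The CS array had an Xist signal of 10.4, while the Air arrays had 3743, 6290 and 3488, although every animal was labelled male. The calls at 5 hr can therefore not be assigned to smoke alone, and no hybridisation session was recorded at that time.

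**Figure D1:**
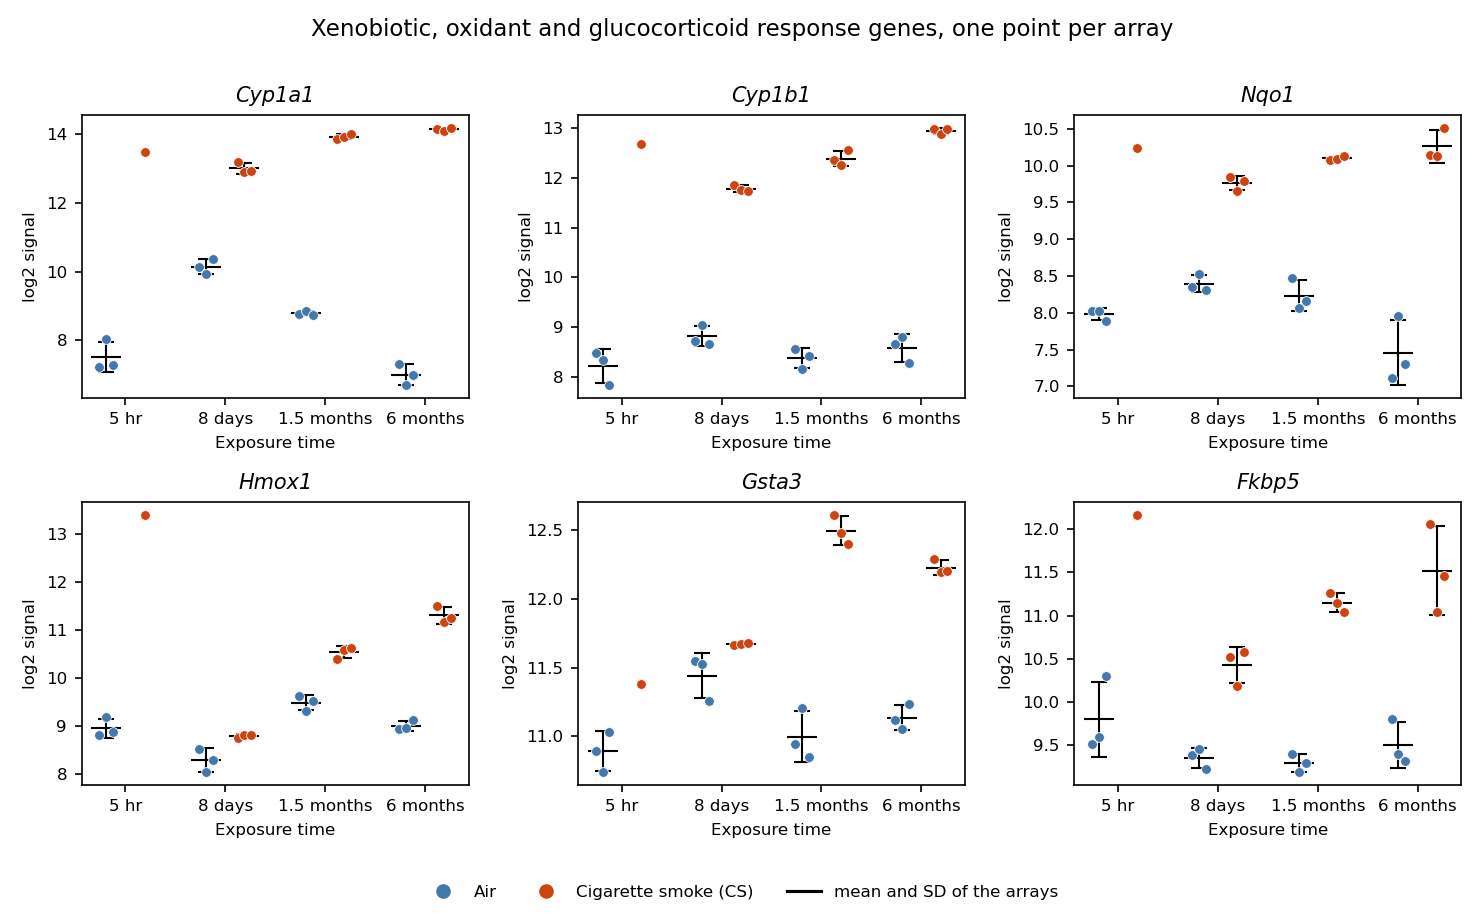
Signal per array, on a log2 scale, of Cyp1a1, Cyp1b1, Nqo1, Hmox1, Gsta3 and Fkbp5 in Air and CS lungs at 5 hr, 8 days, 1.5 months and 6 months; points are arrays and bars are the mean ± SD. Cyp1a1 was higher in CS lungs at every time, by 62.6-fold at 5 hr and 141-fold at 6 months.

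The second comparison asked what 8 days of smoke changed. Both hydrocarbon-oxidising cytochromes rose again: Cyp1b1 went from 451 in Air lungs to 3516 in CS lungs, 7.80-fold, and Cyp1a1 from 1131 to 8209, 7.26-fold. Circadian clock genes were among the large rises: Dbp, an output factor of the clock, rose 14.9-fold, and Nr1d2, a nuclear receptor of the clock, 9.11-fold. Nr1d1, the repressor Rev-erb alpha, went from 41.5, below the 20th percentile of the Air arrays (68.2), to 818, so its fold is not given. Arntl, the activator Bmal1, fell by 1.91 on the log2 scale. For each of these, all 3 CS arrays lay beyond all 3 Air arrays, and the limma adjusted p ranged from 3.2e-12 for Dbp to 5.51e-06 for Arntl.

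The 8-day Air arrays stood apart from all other arrays, and each 8-day group was hybridised in a session of its own. The bacterial and phage spike-in controls averaged 12.35 ± 0.24 (SD, n = 3) on the log2 scale on Air arrays and 11.27 ± 0.14 on CS arrays. This was the largest separation 3 against 3 arrays allow (exact permutation test, two-sided p = 0.1, the smallest possible). The 3' to 5' signal ratio of the actin control was 1.69 against 1.35. Differences at 8 days were therefore also computed against 1.5-month Air lungs, a control chosen after the values were seen. Those Air arrays were of another session and another time than the 8-day CS arrays. This contrast therefore mixes smoke with session and time. Between 8-day and 1.5-month CS lungs 2659 probe sets differed. Of the 4746 genes called against 8-day Air, 136 were called the same way against 1.5-month Air and 259 the opposite way. Both comparisons used the same CS arrays, so these counts are not independent, and they were compared with no count expected by chance.

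Several genes were called the same way against both controls at 8 days. Such agreement does not by itself show an effect of smoke. Against 1.5-month Air, the log2 rise was 4.21 for Cyp1a1, 3.40 for Cyp1b1, 2.16 for Aldh3a1, 2.02 for Ces1g, a carboxylesterase gene, and 1.53 for Nqo1, the quinone reductase. Fkbp5 rose by 1.13 on that measure, Tsc22d3, the glucocorticoid-induced leucine zipper gene, by 0.95, and Gsta2, a glutathione transferase gene, by 1.15. Nr4a1, an immediate early nuclear receptor gene, fell by 1.75 and Tmem119 fell by 1.04. Against 8-day Air, Aldh3a1 was called at 0.98, but not without Air 1, Air 3 or CS 1 (adjusted p = 0.0513, 0.0735 and 0.152). Against 1.5-month Air, the clock genes Dbp and Nr1d1 fell, at -1.06 and -1.48. Per1 and Per2 were 0.39 and 0.51 there and did not pass (adjusted p = 0.0514 and 0.143).

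Other large rises against 8-day Air were Tspan4, a tetraspanin, at 7.71-fold, and Smpd2, a sphingomyelinase, at 6.59-fold. Tspan4 varied between the 8-day Air arrays, with a log2 SD of 1.15 (n = 3). Further genes of the rule rose from an Air signal below the 20th percentile of those arrays, so their folds are not given. These were Ctsf, a lysosomal protease, from 27.6 to 280, Rara, a retinoic acid receptor, from 30.7 to 224, and Slit3, a guidance ligand, from 28.6 to 196. Prmt8, an arginine methyltransferase, went from 32.3 to 216, and Vps33b, of vesicle transport, from 47.7 to 310. Against 1.5-month Air, Ctsf was 0.09 and Smpd2 was -0.07 on the log2 scale. Tspan4 was -0.35, Rara -0.29, Vps33b -0.19 and Prmt8 0.87; none of these passed the test there, while Slit3 fell by 0.97. The largest falls against 8-day Air were Defa39, an intestinal defensin gene, which fell by 2.61, Ntmt1, a methyltransferase, Thbs2, a matrix glycoprotein, Arntl, Vmn1r148, Iglon5, Snhg14 and Tmem229a. Ntmt1 fell by 2.38, while another of its probe sets was called in the opposite direction. Defa39 lost its call without Air 1 (adjusted p = 0.0599) or CS 2 (adjusted p = 0.102).

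In the 8-day lungs 6 gene lists were called, and none held with an estimated correlation. Of 5 aryl hydrocarbon receptor targets 4 rose and Tiparp fell by 0.27, with the same counts adjusted over the list alone and adjusted p = 0.138 with an estimated correlation. Of 30 Nrf2 and glutathione genes 15 rose and 2 fell (16 and 2 adjusted over the list alone). Examples were Osgin1, at 2.71-fold, and Nqo1, at 2.58-fold; Fth1, the ferritin heavy chain gene, fell by 0.70. Of 15 glucocorticoid response genes 9 rose and none fell (10 and 1 adjusted over the list alone), such as Tsc22d3 at 2.23-fold and Per1, also a clock gene, at 2.64-fold. The Nrf2 and glucocorticoid lists both had adjusted p = 0.463 with an estimated correlation. Of 18 clock genes 12 rose and 4 fell, also when adjusted over the list alone, with adjusted p = 0.138 with an estimated correlation.

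Of 18 endothelial markers 13 rose and 1 fell at 8 days (14 and 2 adjusted over the list alone), including Pecam1, an adhesion molecule, at 1.65-fold and Vwf, von Willebrand factor, at 2.10-fold. Adjusted p was 0.575 with an estimated correlation, and Pecam1 was -0.15 and Vwf -0.30 against 1.5-month Air. Of 14 ribosomal protein genes 11 fell (12 adjusted over the list alone), such as Rps14 and Rpl7, at -0.71 and -0.64, with adjusted p = 0.77 with an estimated correlation. Under quantile normalization this list was no longer called (adjusted p = 0.529), Rps14 was -0.09, and Rps18 changed sign. The club cell list (1 risen, 4 fallen of 11; adjusted p = 0.283) and the alveolar type 2 list (5 risen, 3 fallen of 13; adjusted p = 0.565) were not called. Of their members, Scgb1a1, the main secretory protein of club cells, was -1.05, and Sftpc, surfactant protein C, -0.98. Under quantile normalization Scgb1a1 was -0.11 and not called (adjusted p = 0.0626). Neither gene fell against 1.5-month Air, where Scgb1a1 was 0.19 and Sftpc 0.23.

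At 8 days 10290 probe sets were called, 4989 higher and 5301 lower, and 5576 of them changed at least 1.5-fold. With 1.5-month Air as control the count was 1741. The share of higher calls was 48.5%, against 60.2% with quantile normalization and 91% with median centring (12672 higher and 1249 lower). The median difference of all probe sets was -0.05 on the log2 scale, 0.05 with quantile normalization and 0.36 with median centring.

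**Figure D2:**
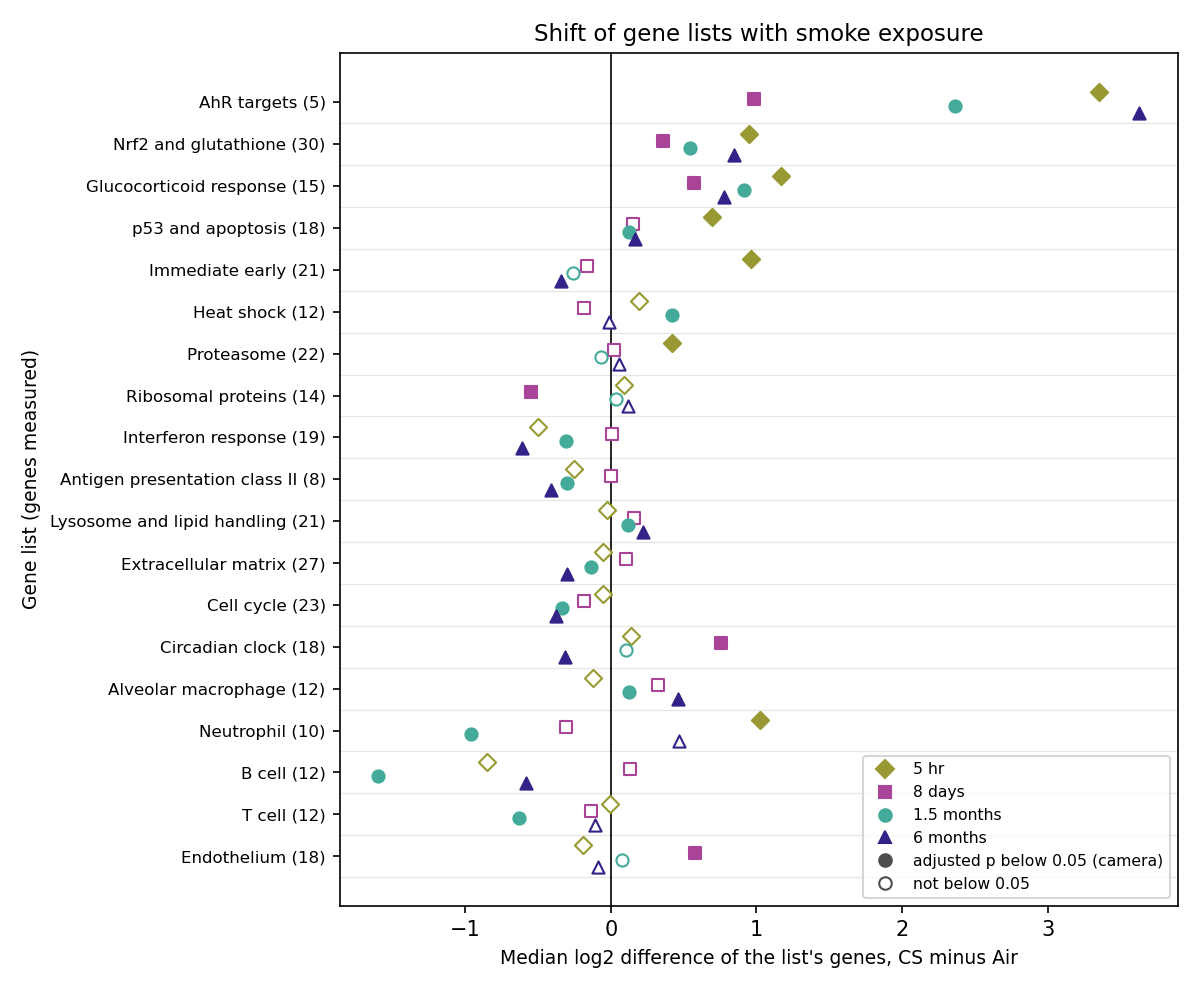
Median log2 difference between CS and Air lungs over the members of 19 gene lists, by time; filled points had camera adjusted p under 0.05. The targets of the aryl hydrocarbon receptor had a median of 3.35 at 5 hr, 0.98 at 8 days, 2.36 at 1.5 months and 3.63 at 6 months, and the B cell list had -1.60 at 1.5 months.

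The third comparison asked what smoke had changed after 1.5 months. Cyp1a1 rose 35.1-fold, from 443 in Air to 15529 in CS lungs, and Cyp1b1 rose 16.0-fold. Ces1g rose 8.63-fold and Nqo1 3.64-fold. B cell genes fell: Cd79a and Cd79b, the signalling chains of the B cell receptor, were -2.01 ± 0.28 (SE) and -1.96 ± 0.33 on the log2 scale. Col1a1, the fibrillar collagen gene, fell by 1.51 ± 0.17. All of these genes separated 3 CS from 3 Air arrays, with limma adjusted p between 1.22e-13 for Cyp1a1 and 0.000681 for Cd79b.

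The remaining large rises at 1.5 months were Fam107a, an actin-binding stress gene, at 5.72-fold, and Slc6a2, the noradrenaline transporter, at 5.59-fold. Aldh3a1 rose 5.14-fold, Zbtb16, a glucocorticoid-induced transcription factor, 4.74-fold, Angptl7 3.69-fold and Fkbp5 3.62-fold. Rab3c, a vesicle GTPase, went from 39.9 to 215 and 9530077C05Rik from 48 to 180, both from near the 20th percentile of 34.1 in Air lungs. The call of 9530077C05Rik was lost without Air 3, where log2 was 0.89, or without CS 1, CS 2 or CS 3 (adjusted p = 0.085, 0.124 and 0.143). Tmem151a fell from 356 to 41.5, near the 20th percentile of CS arrays (33.9). Other large falls were Ighv14-2, an immunoglobulin heavy chain segment, at -2.44, and H2-Ob and H2-DMb2, which regulate peptide loading on class II molecules, at -2.19 and -2.15. Egr1, an immediate early factor, fell by 2.04 and Ms4a4c at -1.96.

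Of 12 B cell genes, 10 fell and none rose at 1.5 months, also when adjusted over the list alone. Bank1, an adaptor, fell by 1.87, Pou2af1, a coactivator in B cells, at -1.71, and Fcmr, the receptor for immunoglobulin M, at -1.68. The list's median was -1.60, its camera adjusted p was 1.06e-13, and adjusted p = 0.0752 with an estimated correlation. Of 8 class II antigen presentation genes 3 fell, also when adjusted over the list alone, with adjusted p = 0.273 with an estimated correlation; H2-Oa fell by 1.22. Of 12 T cell genes 3 fell (8 adjusted over the list alone), including Cd2, an adhesion receptor, at -1.06 and Cd247, the zeta chain of the T cell receptor complex, at -0.96. The estimated-correlation adjusted p was 0.109. Of 10 neutrophil genes 4 fell (6 adjusted over the list alone), such as Hdc, histidine decarboxylase, at -1.18 and Ltf, lactotransferrin, at -0.91, with adjusted p = 0.249 with an estimated correlation. Plasma cell genes fell in 2 of 11 and dendritic cell genes in 1 of 12, Ccr7, which was not called with quantile normalization. Their adjusted p was 0.345 and 0.231 with an estimated correlation.

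Detoxifying genes rose at 1.5 months. All 5 measured aryl hydrocarbon receptor targets rose, also when adjusted over the list alone, with adjusted p = 4.1e-05 with an estimated correlation. Of 30 Nrf2 and glutathione genes 20 rose and none fell (21 adjusted over the list alone), such as Gsta3, a glutathione transferase, at 2.82-fold, Cbr3, a carbonyl reductase, at 2.27-fold, and Txnrd1 at 2.11-fold. Of 15 glucocorticoid response genes 11 rose (12 adjusted over the list alone), such as Tsc22d3 at 2.66-fold and Sult1a1, a sulfotransferase, at 2.64-fold. Adjusted p with an estimated correlation was 0.000852 for the Nrf2 list and 0.00814 for the glucocorticoid list. Of 12 heat shock genes 5 rose (9 adjusted over the list alone), with Hsph1 at 2.52-fold and adjusted p = 0.158 with an estimated correlation. Of 18 genes of the p53 and apoptosis list 4 rose and 1 fell (6 and 1 adjusted over the list alone); Cdkn1a rose 1.88-fold, and adjusted p = 0.184 with an estimated correlation.

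Of 27 extracellular matrix genes 9 fell, 2 rose and 16 did not pass at 1.5 months, with the same falls and rises adjusted over the list alone, with adjusted p = 0.254 with an estimated correlation. Col3a1 fell by 1.25, Loxl1, a lysyl oxidase family member, at -1.11, and Col6a3 at -0.86, while Lox rose 3.03-fold. Of 21 lysosome and lipid handling genes 3 rose (6 adjusted over the list alone): Abca1, a cholesterol exporter, at 1.51-fold, Gpnmb, a glycoprotein of lipid-laden macrophages, at 1.87-fold, and Lpl, lipoprotein lipase, at 1.70-fold. Of 12 alveolar macrophage genes 2 rose, among them Marco, a scavenger receptor, at 2.02-fold. Of 11 club cell genes 2 rose, such as Cyp2b10, a cytochrome, at 1.49-fold. Adjusted p with an estimated correlation was 0.254, 0.273 and 0.254 for these 3 lists. Edn1, the endothelin-1 gene, rose 2.46-fold and Lyve1 2.06-fold.

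Further lists were called at 1.5 months with few or no members passing. Cell cycle genes (0 of 23 passing, 3 fallen when adjusted over the list alone) had a median of -0.34, cytotoxic lymphocyte genes (0 of 12, 4 fallen when adjusted over the list alone) -0.60 and cholesterol and fatty acid synthesis genes (0 of 18) -0.14. Interferon response genes had a median of -0.31, although 1 of its 19 members, Ifit3, was called upward. The thyroid, oesophagus and squamous tissue list, a check for adjoining tissue, had -1.38 with no member passing. Adjusted p with an estimated correlation was 0.273, 0.337, 0.445, 0.59 and 0.445 in turn.

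At 1.5 months 1595 probe sets were called, 788 higher and 807 lower, and 867 changed at least 1.5-fold. The 3 Air arrays and 1 CS array shared a hybridisation session, and the other 2 CS arrays shared another. With session as a fixed block, which compares 1 CS with 3 Air arrays of the same session, 387 probe sets were called. In that fit the B cell list had a median of -1.86 (adjusted p = 5.77e-16), the receptor targets 2.33 and the matrix list -0.04 (adjusted p = 0.015). These are values at the preset correlation from 1 CS array; over all arrays the B cell and matrix lists had adjusted p = 0.0752 and 0.254 with an estimated correlation. The alveolar macrophage, cholesterol, dendritic cell and squamous tissue lists were not called there, with adjusted p = 0.201, 0.0545, 0.0521 and 0.0545.

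**Figure D3:**
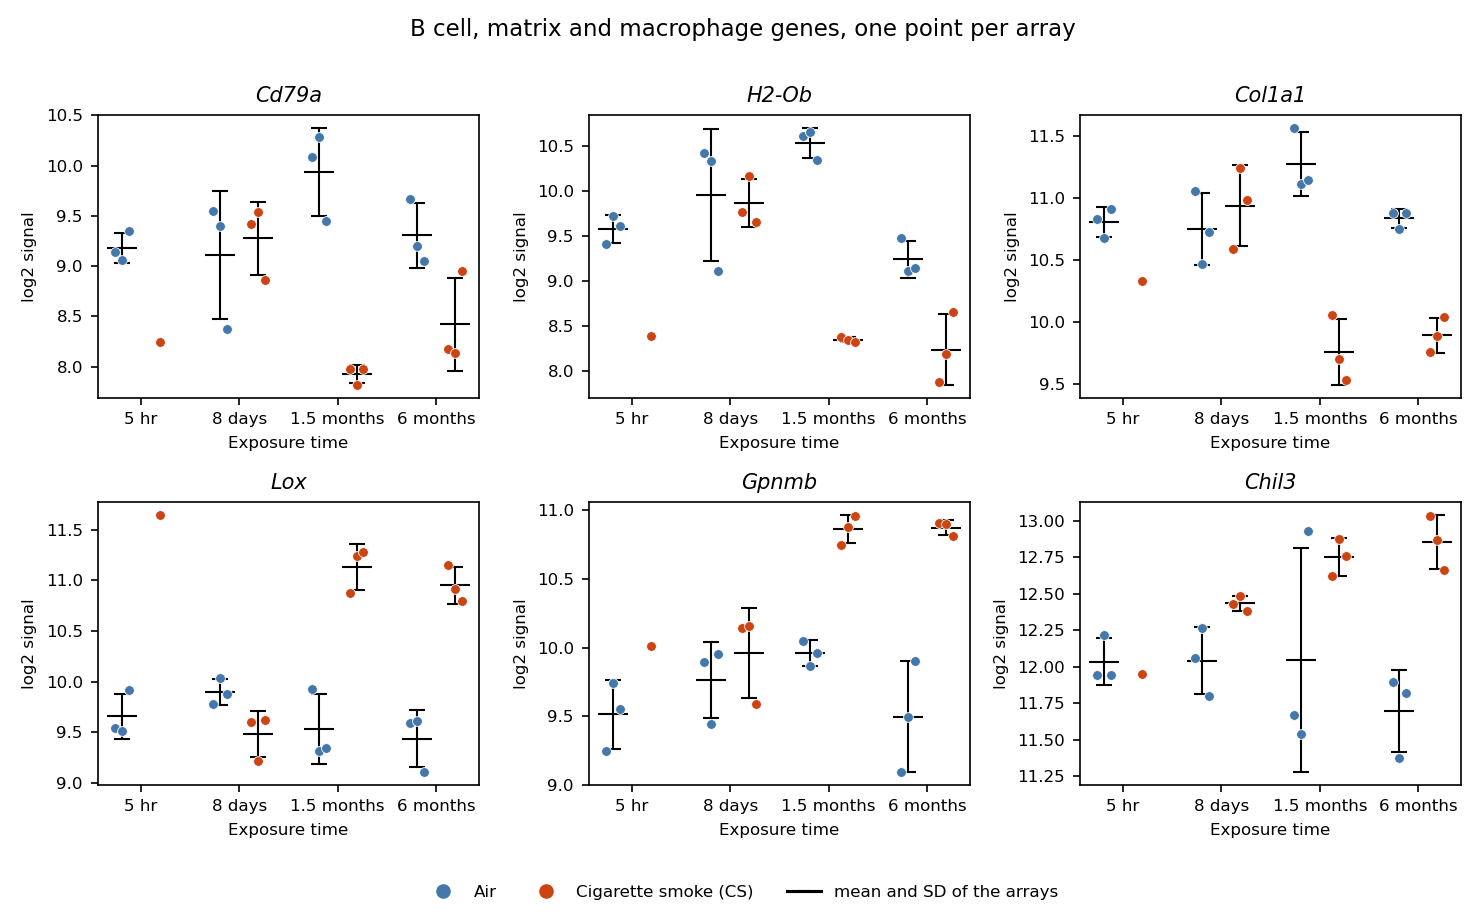
Signal per array, on a log2 scale, of Cd79a, H2-Ob, Col1a1, Lox, Gpnmb and Chil3 in Air and CS lungs by time; points are arrays and bars are the mean ± SD. At 1.5 months Cd79a averaged 982 in Air and 243 in CS lungs, and Col1a1 2477 and 869.

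The fourth comparison asked what 6 months of smoke had changed. Cyp1a1 rose 141-fold, from 128 in Air to 18022 in CS lungs, and Cyp1b1 rose 20.6-fold. Aldh3a1 rose 12.4-fold, Ces1g 8.83-fold, Nqo1 6.97-fold and Hmox1 4.88-fold. Adh7, an alcohol dehydrogenase of epithelium, rose 6.97-fold. Gpnmb, a glycoprotein of lipid-laden macrophages, rose 2.60-fold and Chil3, a chitinase-like protein of alveolar macrophages, 2.23-fold. Dbp fell by 2.45 ± 0.16 (SE) on the log2 scale and Nr1d1 at -2.52 ± 0.25. The limma adjusted p of these genes lay between 2.09e-16 for Cyp1a1 and 0.00632 for Chil3.

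Other large rises at 6 months were Erdr1 at 4.84-fold, Rasl11a, a small GTPase, at 4.26-fold, Fkbp5 at 4.04-fold, Gclm, a subunit of the glutathione-forming ligase, at 3.92-fold and Fam107a at 3.80-fold. The largest falls, besides Nr1d1 and Dbp, were Pmel, a melanosome protein, which went from 155 to 43.7, near background, Acoxl, an acyl-CoA oxidase-like gene, at -1.62, and Scn3b, a sodium channel subunit, at -1.56. Nr4a1 fell by 1.54, Map2k6, a kinase of the p38 route, at -1.39 and Hspa1b, an inducible heat shock protein, at -1.35. In each of these genes the 3 CS arrays lay beyond the 3 Air arrays. Pmel lost its call without Air 1 (adjusted p = 0.0512). Hspa1b lost it without Air 2, Air 3, CS 1 or CS 3 (adjusted p = 0.111, 0.0747, 0.0879 and 0.0929).

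Of 5 aryl hydrocarbon receptor targets 4 rose at 6 months (5 adjusted over the list alone), with adjusted p = 3.49e-05 with an estimated correlation. Of 30 Nrf2 and glutathione genes 23 rose and none fell (25 adjusted over the list alone); Cbr3 rose 3.29-fold and Txnrd1 2.98-fold. The estimated-correlation adjusted p was 3.5e-05. Mt1 and Mt2 rose 2.86-fold and 3.08-fold; their list of 4, of which 1 fell, had adjusted p = 0.0848 with an estimated correlation. Of 15 glucocorticoid response genes 8 rose and 1, Per1, fell (10 and 1 adjusted over the list alone). Of 18 p53 and apoptosis genes 3 rose (5 adjusted over the list alone), including Cdkn1a at 2.55-fold. Both of these lists had adjusted p = 0.0715 with an estimated correlation.

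Of 21 lysosome and lipid handling genes 7 rose, none fell and 14 did not pass at 6 months, also when adjusted over the list alone. Examples were Abca1 at 1.57-fold, Gpnmb at 2.60-fold and Lgals3, galectin-3, at 1.46-fold. Of 12 alveolar macrophage genes 3 rose, 1 fell and 8 did not pass, with the same counts adjusted over the list alone. Both lists had adjusted p = 0.0848 with an estimated correlation. Of 20 protease and inhibitor genes 4 rose and 1 fell (5 and 1 adjusted over the list alone): Mmp8, a collagenase of neutrophils, rose 2.36-fold, Ctsk, cathepsin K, 1.71-fold and Adam8 1.74-fold, while Adamts1 fell by 0.92. Clec4d, a lectin of myeloid cells, rose 2.48-fold, whereas Hdc fell by 0.94. Of 8 neutrophil chemokine and acute phase genes 1 rose (2 adjusted over the list alone). The adjusted p with an estimated correlation was 0.258 for proteases and 0.296 for chemokines.

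Some interferon, matrix and cell cycle genes fell at 6 months, while most members of these lists did not pass. Of 19 interferon response genes 5 fell (10 adjusted over the list alone), including Ifit2, an inhibitor of translation, at -0.92, Bst2, tetherin, at -0.82 and Usp18, a deconjugase of Isg15, at -0.77. The adjusted p was 0.346 with an estimated correlation. Of 27 extracellular matrix genes 7 fell and 2 rose (13 and 2 adjusted over the list alone), with adjusted p = 0.196 with an estimated correlation. Col3a1 fell by 0.96 and Col1a1 at -0.94, while Lox rose 2.86-fold and Eln 1.62-fold. Of 13 fibroblast and pericyte genes 5 fell and 1, Ces1g, rose (6 and 1 adjusted over the list alone), with adjusted p = 0.237 with an estimated correlation. Of 23 cell cycle genes 4 fell (8 adjusted over the list alone), with Mki67, a marker of dividing cells, at -0.97 and adjusted p = 0.202 with an estimated correlation. Emcn, a sialomucin of capillaries, fell by 0.84 and Bmp4, a growth factor, at -0.65, while Lyve1 rose 2.28-fold.

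Of 18 clock genes 7 fell and 1, Arntl, rose at 6 months (8 and 3 adjusted over the list alone), with adjusted p = 0.0715 with an estimated correlation. Ciart, a repressor of the clock, fell by 1.18 and Nr1d2 at -0.74. Of 21 immediate early genes 5 fell and 1 rose (7 and 2 adjusted over the list alone), such as Klf2, at -0.94, with adjusted p = 0.392 with an estimated correlation. Of 12 B cell genes 1 fell (4 adjusted over the list alone; adjusted p = 0.445 with an estimated correlation), and 2 of 8 class II genes fell (4 adjusted over the list alone; adjusted p = 0.346 with an estimated correlation). Cytotoxic lymphocyte genes had a median of -0.52 with no member of 12 passing (adjusted p = 0.445 with an estimated correlation). Mitochondrial respiration genes (0 of 18) had a median of 0.20, cardiac muscle genes (0 of 12) 0.52, erythroid genes (0 of 4, 3 risen when adjusted over the list alone) 0.53 and club cell genes (1 of 11) 0.11. Their adjusted p with an estimated correlation was 0.471, 0.621, 0.4 and 0.467. Acta1 varied from 326.9 to 11400 between the 6-month CS arrays.

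At 6 months 1447 probe sets were called, 619 higher and 828 lower, and 763 changed at least 1.5-fold. With session as a fixed block, again 1 CS against 3 Air arrays of the same session, 554 were called, and with median centring 924. In the session fit the receptor targets had a median of 3.69, the Nrf2 list 0.88, the interferon list -0.38 (adjusted p = 0.0207) and the B cell list -0.82 (adjusted p = 4.14e-05), at the preset correlation. Over all arrays the interferon and B cell lists had adjusted p = 0.346 and 0.445 with an estimated correlation. The neutrophil chemokine, protease, club cell and fibroblast lists were not called there, with adjusted p = 0.0721, 0.0721, 0.0642 and 0.0791.

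The fifth comparison took the mean of the differences at 8 days, 1.5 months and 6 months, to describe the response to continued smoke. On average Cyp1a1 was 5.04 ± 0.10 (SE) log2 units higher in CS lungs, Ces1g 2.74 ± 0.10, Aldh3a1 2.32 ± 0.19 and Nqo1 2.01 ± 0.10. Fkbp5 averaged 1.65 ± 0.12, and Nr4a1 was lower, at -1.30 ± 0.13. The receptor target, Nrf2 and glucocorticoid lists were called and held with an estimated correlation, with adjusted p = 0.000213, 0.000454 and 0.0115. Of their members 5 of 5, 26 of 30 and 14 of 15 rose, and adjusted over the list alone 5, 26 and 14 rose. In all, 17 of 48 lists were called, 9 upward and 8 downward. B cell genes fell in 9 of 12 (10 adjusted over the list alone) with adjusted p = 0.268 with an estimated correlation. Lysosome genes rose in 10 of 21 (12 adjusted over the list alone) with 0.133. The B cell fall was uneven over the times. The list's median CS difference changed by -1.27 from 8 days to 1.5 months and by 0.95 from 1.5 to 6 months. With an estimated correlation, camera adjusted p was 0.603 and 0.235 for these changes. At 8 days Cd79a was 8.86 to 9.54 on the log2 scale in CS lungs and 8.38 to 9.55 in Air lungs.

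The mean over 3 times called 5570 probe sets, 2863 higher and 2707 lower, and 708 of these changed at least 1.5-fold. Without the 8-day difference 2669 were called. With median centring 8610 were called, 7783 higher and 827 lower. Called upward on average at 8 days, 1.5 and 6 months, the circadian and endothelial lists had medians of -0.08 and -0.01 without 8 days and were not called.

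Genes called at several times were counted next. No control array was shared between times, but all calls came from 1 fit with 1 estimate of the spread per probe set. The expected counts and Fisher's test below assume independent calls, which such a fit does not give. Between 1.5 and 6 months 139 genes were higher at both, against 12 expected by chance, and 155 lower at both, against 18.6 (Fisher's exact test, two-sided p = 7.4e-116 and 7.22e-105). Differences at these times correlated with Pearson's r of 0.301 across genes, which are not independent replicates. Between 8 days and 6 months 113 genes were higher at both (69.3 expected) and 51 lower at both (79.9 expected, exact p = 0.00018), 155 were higher at 8 days and lower at 6 months, and r was -0.104. Between 8 days and 1.5 months 230 were higher at both (94 expected) and 76 lower at both (78.3 expected, exact p = 0.802), and r was 0.156. At 8 days, 1.5 and 6 months 70 genes were higher each time and 22 lower, against 2.45 and 2.99 expected. At all 4 times 49 were higher and 11 lower, against 0.195 and 0.514 expected. The shared higher genes held Cyp1a1, Cyp1b1, Nqo1, Hmox1, Gsr, the glutathione reductase gene, and Pgd, of the pentose phosphate route. They also held Abca1, Lyve1 and Sqstm1, an autophagy adaptor. Those lower at all 4 times held Sox4, a transcription factor, Rasgrp3, a Ras activator, and Tmem119. The 8-day calls in these counts are against the 8-day Air arrays, which stood apart. Of 4746 genes called there, 136 were called the same way and 259 the opposite way against 1.5-month Air. Hmox1 was 8.75 to 8.83 on the log2 scale on 8-day CS arrays. It was 8.05 to 8.53 on 8-day Air arrays and 9.31 to 9.62 on 1.5-month Air arrays.

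Whether the CS difference itself varied between 8 days, 1.5 months and 6 months was tested as an interaction. The 6 genes with the smallest adjusted p were Dbp, Nr1d2, Nr1d1, Cyp1a1, Smpd2 and Eln, between 3.11e-13 and 1.28e-07. From 8 days to 1.5 months the CS difference of Dbp went from 3.89 to -1.94 on the log2 scale. Over the same interval that of Nr1d2 went from 3.19 to -0.16, and that of Smpd2 from 2.72 to 0.34. For Dbp and Nr1d2 most of this change lay in Air lungs. Signal at 8 days minus that at 1.5 months was -4.96 and -3.40 in Air lungs, and 0.88 and -0.05 in CS lungs. The rise of Smpd2 at 8 days was not seen against 1.5-month Air (above), so most of its change also lay in Air lungs. The 8-day difference of Nr1d1 rests on an Air signal below the arrays' 20th percentile, so its change is given only in direction, from higher to lower in CS lungs. The difference of Eln went from -0.98 to 0.42. The difference of Cyp1a1 grew from 2.86 through 5.13 to 7.14 at 6 months. At 8 days Cyp1a1 also had its highest Air signal, 1131, against 183 at 5 hr, 443 at 1.5 months and 128 at 6 months.

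In total 6980 probe sets varied between the 3 times. Between 1.5 and 6 months alone 131 did, which covered 71 genes, and 3464 had an unadjusted p under 0.05. The 1.5-month arrays carried Y-linked signal and the 6-month arrays Xist signal, so time was confounded with sex-linked signal in this change. The differences of Cyp1a1 and Hmox1 grew, by 2.00 ± 0.24 (SE) and 1.23 ± 0.18 on the log2 scale (adjusted p = 0.000731 and 0.00401). From 1.5 to 6 months the signal of Cyp1a1 went from 15529 to 18022 in CS lungs and from 443 to 128 in Air lungs, so most of its growth came from the lower Air signal. That of Hmox1 went from 1485 to 2523 in CS lungs and from 716 to 517 in Air lungs. The difference of Erdr1 grew by 2.09 ± 0.26. Per1 fell by 1.32, from 0.62 to -0.70, and Hsph1 fell by 1.73, from 1.33 to -0.40. Among lists, Nrf2 and glutathione genes gained a median of 0.34 between 1.5 and 6 months (camera adjusted p = 6.39e-10, and 0.0536 with an estimated correlation). The clock list fell by 0.56 (adjusted p = 1.51e-06, and 0.0536 with an estimated correlation). No list was called for this change with an estimated correlation. Upward were the neutrophil list, by 1.10 (0.139 with an estimated correlation), the T cell list, by 0.49 (0.215), and the erythroid list, by 1.02 (0.235). Neutrophil chemokines rose by 0.40 (0.153), mitochondrial respiration by 0.18 (0.596) and proteasome genes by 0.11 (0.616). Downward lists had medians of -0.48 for glucocorticoid response (0.495), -0.31 for interferon (0.667) and -0.15 for endothelium (0.503). Vascular signalling had -0.14 and unfolded protein -0.11 (both 0.323). Lists of other tissue also went up: cardiac muscle by 0.78 (0.616), skeletal muscle by 2.35 (0.667) and squamous tissue by 2.29 (0.495). The B cell list went up by 0.95 (adjusted p = 8.15e-07, and 0.235 with an estimated correlation) and the heat shock list fell by 0.44 (adjusted p = 1.2e-07, and 0.139 with an estimated correlation). The B cell change is in the CS minus Air difference and does not by itself show a recovery in CS lungs. Its member Cd79a was 7.82 to 7.98 in CS lungs at 1.5 months and 8.13 to 8.95 at 6 months. In Air lungs Cd79a was 9.45 to 10.28 and then 9.05 to 9.66.

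The last comparison asked how Air lungs varied over time. Among genes chosen after the values were seen, the clock gene Dbp averaged 12.37, 7.13, 12.09 and 12.13 on the log2 scale in Air lungs at 5 hr, 8 days, 1.5 months and 6 months (adjusted p = 1.62e-14). Nr1d1 averaged 10.99, 5.38, 11.15 and 10.70, and Arntl ran the other way, with 7.07, 10.04, 7.55 and 7.20. In all 18710 of 27022 probe sets varied, 8092 without the 8-day arrays and 1540 between 5 hr and 6 months alone. The 5 hr and 6-month Air arrays had Xist signals from 2944 to 6290, and the 8-day and 1.5-month Air arrays from 5 to 37.6. The Y-linked gene Eif2s3y read at most 13.8 on the former and at least 640.4 on the latter. Between times with like sex-linked signal, 1540 probe sets differed from 5 hr to 6 months and 13804 between 8 days and 1.5 months. Air arrays at 8 days, 1.5 and 6 months were hybridised in different sessions, so time could not be separated from session there.

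**Figure D4:**
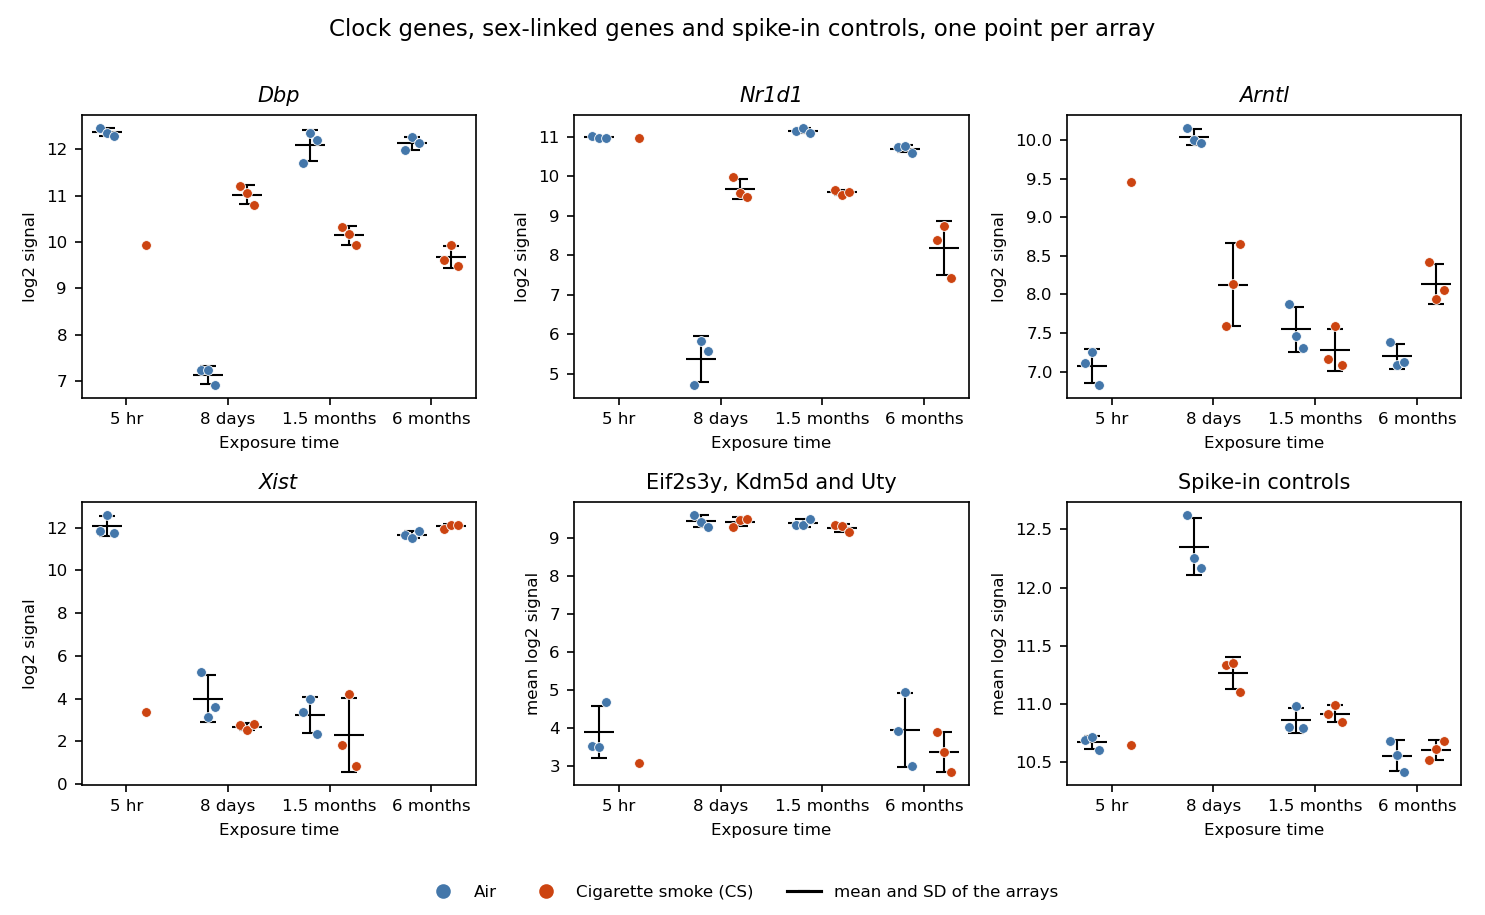
Signal per array, on a log2 scale, of the clock genes Dbp, Nr1d1 and Arntl, of Xist, of the mean of 3 Y-linked genes and of the spike-in controls, by group and time; points are arrays and bars are the mean ± SD. Dbp was lowest on the 8-day Air arrays, at 7.13, where the spike-in controls were highest, at 12.35.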

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

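The tests of hybridisation, clock phase and sex-linked genes in this part were chosen only after the results were seen, while the counts over other splits of the arrays were planned. Between 8 days and 1.5 months the CS difference of several genes changed, by the test of that change itself. On the log2 scale the change was -5.84 for Dbp, -3.35 for Nr1d2, -5.86 for Nr1d1, 2.27 for Cyp1a1, -2.38 for Smpd2 and 1.40 for Eln; the value of Nr1d1 rests on an 8-day Air signal of 41.5, below those arrays' 20th percentile of 68.2, and has no exact size. Of these 6 only Cyp1a1 also changed between 1.5 and 6 months. The CS difference of 6980 probe sets varied over 8 days, 1.5 and 6 months, and that of 131 varied between 1.5 and 6 months.

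The first pattern is the larger number of calls at 8 days (10290) than at 1.5 months (1595) or 6 months (1447). A larger response to 8 days of smoke as the whole account is argued against by the Air lungs: 13804 probe sets differed between 8-day and 1.5-month Air, and 2659 between 8-day and 1.5-month CS. The spike-in controls, added apart from the lung RNA, were 1.09 log2 units higher on 8-day Air than on 8-day CS arrays, which is consistent with weaker labelled target on the Air arrays, although this does not show that the target made the calls. Hybridisation session cannot be told apart from exposure at 8 days, since 0 sessions held both groups. A biological difference of the 8-day Air lungs, such as in age or time of collection, stays open. Age was not tested, and the clock genes below bear on time of collection without giving the hour.

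The second pattern is the clock, where smoke as the only source at 8 days is argued against by Air lungs, where Dbp at 8 days was -4.96 ± 0.16 (SE) log2 units from that at 1.5 months with no smoke in either group. At 6 months the CS differences of 18 clock genes correlated with this smoke-free difference (Pearson's r 0.918, Spearman's rho 0.825, across genes, which are not independent), and r was 0.792 without Dbp and Nr1d1. This is consistent with a different clock phase at collection of the 6-month CS and Air lungs. At 1.5 months r was 0.683, and 0.195 without Dbp and Nr1d1, with a reference that shares its Air arrays, and 0.552 and -0.0578 against 8-day minus 6-month Air, which shares none; at 5 hr, with 1 CS array, r was 0.595 with and without those genes. An action of smoke on the clock stays open, because the hour of collection is not given in the sources used here.

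The third pattern is the sex-linked signal of animals all labelled male. The 9 arrays of 5 hr Air and of both 6-month groups had Xist signal, and their highest mean of 3 Y-linked genes lay 4.21 log2 units below the lowest of the 12 arrays at 8 days and 1.5 months (difference -4.21). This is consistent with female animals in those groups. The 5 hr CS array had neither signal, and its score for genes that escape X inactivation was 0.181, on a scale where arrays with Y signal average 0 and those with Xist 1 (SD 0.159). An animal with 1 X and no Y chromosome therefore cannot be told apart from other accounts on 1 array. Smoke and Air lungs were alike in these signals at 8 days, 1.5 months and 6 months, and not at 5 hr.

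Counts of calls were compared with other splits of the arrays. At 8 days 1 of 10 splits, the real one, gave as many calls as 10290, and the highest other gave 2. At 1.5 months it was 1 of 10 (1595, highest other 0), and at 6 months 1 of 10 (1447, highest other 1). With 3 against 3 arrays the splits are too few for a share under 0.05. For the mean over times 1 of 100 splits reached 5570 (highest other 3977), for the change between times 1 of 100 reached 6980 (highest other 6239), and for Air over time 1 of 100 reached 18710 (highest other 10417). For these last 3 counts no other split drawn gave as many calls. The real split also followed session at 8 days, and session and sex-linked signal over time in Air lungs. The counts over splits therefore do not show that smoke or time made the calls.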

How the results depend on the processing

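The alternatives without 8-day arrays or with other Air controls, and the lists with session as a block or with no filter, were chosen after seeing the data; all others were fixed before the data were examined. Of 446 gene results under 1338 other scalings or offsets, 1162 kept direction and call, 169 lost the call and 7 changed sign. With 1 array left out, 1978 of 2328 kept both, 350 lost the call and 0 changed sign. Signs changed at 8 days under quantile normalization for Cst3 (0.0205), Rps18 (0.0408) and Inmt (0.0505), and under median centring for Hspa5 (0.00882), Hspb1 (0.0482), Cox6a1 (0.0300) and Synpo2 (0.0296), none of them called there. Without 8 days the medians of the circadian and endothelial lists changed sign, to -0.0816 and -0.00639, and the monocyte and lymphocyte chemokine list lost its call (adjusted p = 0.107). Of 78 called lists 14 held with an estimated correlation, 65 with quantile normalization, 71 with the mean of all probe sets of a gene and 77 with no filter; of 42 with session as a block 34 held. Quantile normalization ended the calls of mitochondrial respiration (adjusted p = 0.0717) and cardiac muscle (0.0994) at 5 hr, receptor targets (0.0601) and ribosomal proteins (0.529) at 8 days, dendritic cells (0.0822) and squamous tissue (0.053) at 1.5 months, and neutrophil chemokines (0.132), proteases (0.104) and club cells (0.247) at 6 months. It also ended those of monocyte chemokines (0.0724), cell cycle (0.0724), T cells (0.134) and endothelium (0.228) for the mean over times.

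Counts outside 1.5 times the reported ones were as follows; the cause was not tested unless the setting itself tests fewer probe sets or arrays or adds a criterion. Median centring gave 924 at 6 months and 8610 for the mean over times, and array weights 4041 at 1.5 months. With 1 probe set per gene, which tests fewer probe sets, the counts were 3420 at 5 hr, 4723 at 8 days, 2935 for the mean, 3451 for the interaction and 8674 for Air over time. The arrays of both 5 hr groups alone gave 3266. Session as a fixed block, which leaves 1 CS array, gave 387 at 1.5 months and 554 at 6 months. A 1.5-fold minimum left 5576, 867 and 763 at 8 days, 1.5 and 6 months, and left 82 genes shared by 8 days and 1.5 months, 45 by 8 days and 6 months, 142 by 1.5 and 6 months and 27 by all of them. The rule close to the design text gave 4238, 901 and 797, and 1728, 204 and 27 with adjusted p. Without 8 days the mean had 2669, the interaction 131 and Air over time 8092, or 1540 between 5 hr and 6 months; 1.5-month Air as control gave 1741 at 8 days.

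Leaving out 1 array gave 5491 to 5769 at 5 hr, 7456 to 9800 at 8 days, 966 to 1241 at 1.5 months, 857 to 1254 at 6 months, 4515 to 6413 for the mean, 4760 to 7379 for the interaction and 17283 to 18524 for Air over time. The count moved by over 1.5 times at 1.5 months without Air 1 (966), CS 2 (985) or CS 3 (983), and at 6 months without Air 2 (857), CS 1 (959) or CS 3 (900). The share of higher calls was 48.5% at 8 days, 60.2% with quantile normalization, 91% with median centring and 63.5% with the 60% dimmest probe sets left out. At 5 hr it was 35% and 65.2% with median centring, and for the mean 51.4% and 90.4%. Replicate numbers did not pair the samples at every time. The deviations of same-numbered CS and Air arrays from their group means were correlated across probe sets. At 8 days these correlations were 0.069, 0.084 and 0.163, and each CS array correlated best with its own number. They were -0.141 to 0.069 at 1.5 months and -0.093 to 0.053 at 6 months. With the replicate block as fixed terms 3171 probe sets were called at 5 hr, 9774 at 8 days, 1191 at 1.5 months and 1064 at 6 months; no other count moved by over 1.5 times. With session as a random block the counts were 2119 at 1.5 months and 1977 at 6 months, within 1.5 times. Dim probe sets near background limit what can be seen; 73 listed genes lay below the filter.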

Other observations

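The genes in this part were picked after the data were examined. The tests of the CS differences, the interaction and the lists were planned, and the list with session as a block was not. Some genes outside the named rule, picked from those called at several times, fell in smoke-exposed lungs; they form no tested list. Vcam1, an adhesion molecule for leukocytes, was -0.48, -0.72 and -0.64 on the log2 scale at 8 days, 1.5 months and 6 months (limma adjusted p = 0.00207, 0.000222 and 0.00104). Cd83, of activated dendritic cells, was -0.39, -0.80 and -0.83. Adgre4, a receptor of macrophages, fell at all 4 times, at -1.03, -0.45, -0.82 and -1.10. Plac8, of myeloid cells, fell by 1.23 at 1.5 months and was -1.01 at 6 months. Of those that rose at 8 days, 1.5 and 6 months, Ackr2, a scavenger of inflammatory chemokines, went up by 1.01, 0.65 and 0.38. Cebpb, a transcription factor, went up by 0.46, 0.36 and 0.34. All 8-day values in this paragraph are against the 8-day Air arrays, which stood apart. Of 4746 genes called there, 136 were called the same way and 259 the opposite way against 1.5-month Air.

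By value, not all oxidant-response genes had their largest difference at the same time. The order of the times was not tested, and the 5 hr differences rest on a single CS array. Gclc was 2.60 at 5 hr, 0.22 at 8 days (adjusted p = 0.12), 1.15 at 1.5 months and 1.57 at 6 months on the log2 scale, and Srxn1 3.29, 0.09 (adjusted p = 0.628), 0.58 and 1.28. The CS difference of both genes varied over 8 days, 1.5 and 6 months (limma interaction F-test, adjusted p = 2.5e-05 for Gclc and 0.000508 for Srxn1). That test covers these times together and does not single out 8 days. The 8-day differences are against the 8-day Air arrays, which stood apart. Gsta3 was 11.66 to 11.67 on 8-day CS arrays, 11.25 to 11.55 in 8-day Air and 10.85 to 11.20 in 1.5-month Air. Nqo1 was 2.25, 1.37, 1.86 and 2.80 in turn, and Gsta3 0.49, 0.23, 1.50 and 1.09.

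Skeletal muscle transcripts varied within groups. Acta1 read 11645 on 1 of the 8-day CS arrays and 138.6 and 199.5 on the others, and 7318 on 1 of the 1.5-month Air arrays against 631.2 and 174.8 on the others.

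The fall of B cell genes at 1.5 months may come from fewer B cells or from less lymphoid tissue in the lungs sampled. With session as a fixed block, where 1 CS array was compared with 3 Air arrays, the list's median was -1.86; 1 array does not exclude the session. Counts of B cells in matched lung sections would help to separate these accounts. Part of the Cd79a and Col1a1 differences may lie in the 1.5-month Air lungs. On the log2 scale Cd79a was 9.45 to 10.28 there and 8.38 to 9.66 in the other Air groups. Col1a1 was 11.11 to 11.57 there and 10.47 to 11.05 in the other Air groups. The 1.5-month CS arrays lay below all of these, at 7.82 to 7.98 for Cd79a and 9.53 to 10.05 for Col1a1. The cause of the lower collagen signal was not tested. On the CS array that shared a session with Air lungs, Col1a1 was 10.05 against 11.11 to 11.57 at 1.5 months on the log2 scale, and the fibroblast and pericyte list was not called at that time (1 risen, 3 fallen of 13, adjusted p = 0.35).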
